A study of Homo sapiens with 10 samples.

How the data were processed

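Cells sorted as lacking the epithelial marker EPCAM, the endothelial marker CD31 (gene PECAM1) and the leukocyte marker CD45 (gene PTPRC) were collected from lungs of 5 people with idiopathic pulmonary fibrosis (IPF) and 5 healthy donors, and single cell RNA-sequencing was run on them, 1 library per donor. The donor is the replicate throughout, and libraries carry the group and the number in the submitters' titles (IPF 1 to 5; healthy 1, 2, 4, 5 and 6). Per the submitters' processing notes, Cell Ranger 1.3.1 and Seurat 3.0.0 were used; the notes give neither tool a role, and the genome build is not given in the sources used here. Of the 10 deposited tables, 2 (IPF 3 and healthy 5) hold raw UMI counts per gene and cell. In the other 8 deposited tables the values are a normalized signal: the authors divided UMI counts by a size factor per cell, so that every cell of a table sums to one constant, and genes with no UMI in any cell are missing. Dividing each cell's values by its smallest value gave whole numbers for 100% of the values (tolerance 0.01), and these recovered UMI counts were used for all 10 libraries on one scale.

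Genes were matched by the Ensembl identifier in the tables. Of 25195 genes with a UMI, 24942 identifiers are in GENCODE release 29, which served only to find genes of chromosome Y. Gene symbols are those of the deposited tables, and 26 identifiers share a symbol with another. XIST, TSIX and Y-linked genes were left out of every table and test. Of 3676 deposited cells, 3630 had at least 200 genes detected and at most 20% of UMIs from mitochondrially encoded genes and were kept; 38 IPF cells and 8 healthy cells were left out. Total UMIs per library ran from 1992619 to 10835380 and median UMIs per cell from 4011.5 to 25628. Intervals on shares of cells are 95% Wilson intervals, and where no cell had a UMI the upper limit that a count of 0 allows is 3 counts of the total; both cover counting error only.

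Cells were clustered with scanpy 1.11.5 (UMIs per 10000 per cell, natural log, 2000 variable genes found over donors, scaling within each donor, 30 principal components, 20 neighbours, Leiden at resolution 1 with igraph 0.11.9, seed 0). A cluster was named when at least 2 markers of a fixed list were among its 25 leading genes and at least 3 were raised at least 2-fold over the other cells and detected in at least 25% of its cells; a name says which markers were present, hence fibroblast-like, mural-like (smooth muscle or pericyte markers), epithelial-like and so on. Fibroblast-like cells are the clusters with lipofibroblast, adventitial, inflammatory or open subtype names; no cluster was named myofibroblast or proliferating. A cluster stayed unnamed where it met no list, where its 10 leading genes held more markers of another class than of its own (1 cluster, which met the epithelial list), or where its cells had under 0.333 of the median UMIs of their donors with no marker among those 10.

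The design was written before the data were examined: the tests, 40 gene lists (23 lists of pathways and gene families and 17 lists of cell type markers), 64 alternatives and the rule for named genes. It gave edgeR as the main test if all tables held counts and limma otherwise; since 8 tables hold normalized values, limma 3.58.1 was the main test. Per gene and donor, CPM values (a gene's share of the UMIs of a cell on the usual CPM scale) were averaged over the donor's cells, and lmFit and eBayes (trend and robust off) were run on log2 of this mean plus 5 CPM, for genes with a mean over donors of at least 10 CPM, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences on this log2 scale, IPF minus healthy, so they are smaller than plain ratios for genes near 5 CPM. A comparison within a class took donors with at least 20 cells of the class and needed 3 donors per group. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on UMIs summed per donor were run beside it. Lists with at least 3 measured genes were tested by camera (limma) with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were run beside it. Shares of cells were compared by exact two-sided permutation tests over all 252 splits of the 10 donors, for which the smallest possible p is 0.00794.

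The rule for named genes took, per comparison and direction, the 10 genes with the largest fold change among those past the threshold with a mean of at least 20 CPM in the higher group; where fewer passed, the genes with the smallest p filled up to 5 and are given with their values as not past it. It also took up to 3 members of each list by smallest p. Genes whose level in 1 donor can follow common deletions, haplotypes or clonal rearrangement (HLA and drug-metabolism genes, and immunoglobulin and T cell receptor segments) were never named; for the same reason MICA, which the rule took, is given without values.

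The tests were tried on simulated data with the real depths and the spread between the real donors. Of 50 genes changed 4-fold, limma recovered 74% in all sorted cells and 62% in fibroblast-like cells; of 50 changed 2-fold, it recovered 28% and 6%. DESeq2 called 132 and 106 unchanged genes in these runs and limma 12 and 8, so DESeq2 counts are given beside the main ones only as alternatives. camera called a planted list of 15 genes changed 2-fold and 0 of 39 unchanged lists in each run. Simulated genes varied independently of each other, and the unchanged lists were random genes. These runs therefore do not show how often camera calls unchanged lists of correlated genes.

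Alternatives covered the pseudocount, the filter on low values, the cell filter, scaling with TMM factors, donor weights, doublet calls (Scrublet), clustering settings, cells thinned to 2000 UMIs, the 2 raw tables and each donor in turn; 6 further alternatives (5 leaving out IPF 1 and healthy 1 together, and list tests on the donors with shared numbers in an unpaired fit) were added after seeing the data. In fibroblast-like cells the deviations of same-numbered donors from their group means correlated at 0.810, 0.594 and 0.190 for numbers 1, 2 and 4, each best with its own number. By the rule used (each correlation over 0.1) the numbers pair these donors; the numbers are those of the titles, and the labels do not say that they mark a shared batch. Blocked values are therefore given in that comparison where they change a call. No test of mural-like cells, nor of the difference between fibroblast-like and mural-like cells, was made, because only IPF 1, IPF 3 and healthy 1 held 20 mural-like cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.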

Results

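Single cell transcriptomes were collected from sorted mesenchymal cells of 10 human lungs to study the fibroblast lineage and its subtypes in health and in idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung. There were 5 libraries from IPF lungs and 5 from healthy lungs. The 3676 deposited cells carried 48468745 UMIs. IPF 1 to IPF 5 held 517, 157, 555, 69 and 104 cells, and healthy 1, 2, 4, 5 and 6 held 1314, 350, 180, 213 and 217 cells. Total UMIs per library ran from 1992619 in IPF 4 to 10835380 in IPF 3, and the median per cell from 4011.5 in healthy 1 to 25628 in IPF 5. After filtering, 1364 IPF cells and 2266 healthy cells remained. All levels below are mean CPM over the cells of a donor.

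The first comparison asked which mesenchymal cell types and fibroblast subtypes the lungs held and whether their shares differed in IPF. Fibroblast-like cells made up 35.4% ± 20.4 of cells in IPF and 27.4% ± 16.7 in healthy lungs (SD, n = 5 and 5). Shares are of all cells past the filter, also those in unnamed clusters. The latter held 22.9% ± 13.1 of IPF cells and 43.8% ± 28.3 of healthy cells, with 80.4% of healthy 5. Shares of named classes were therefore lowered more in healthy lungs on average. In 8 of the 10 libraries the main fibroblast-like type was named inflammatory. It was led by CXCL8, MMP1 and IL11, genes for a neutrophil attractant, a collagenase and a cytokine. CXCL5, another neutrophil attractant gene, led the largest of these clusters but was not a leading gene of that of IPF 4 and healthy 4. The marker list behind the name holds no general fibroblast gene. The matrix gene DCN was at 67.3 CPM over all cells of IPF 5 against 6381 in IPF 1. COL1A2, COL6A1 and COL6A2 together were at 1181 CPM in fibroblast-like and 113 in epithelial-like cells of IPF 5. The share of inflammatory fibroblast-like cells was 19.5% ± 15.5 in IPF and 16.3% ± 9.95 in healthy lungs. Lipofibroblast-like cells, which carry markers of lipid-storing alveolar fibroblasts such as RGCC, INMT and GPC3, came almost wholly from healthy 1. That library held 396 of the 402 cells of their cluster, a share of 30.2% of its cells (95% Wilson interval 27.8 to 32.7). Adventitial fibroblast-like cells, named for markers of the vessel and airway sheath such as PLA2G2A, MFAP5 and SFRP2, came almost wholly from IPF 1. That library held 116 of 117 cells of their cluster, a share of 23.9% (20.3 to 27.9). Fibroblast-like cells of open subtype made up 40.0% of IPF 1 (35.7 to 44.4) and 19.1% of healthy 1 (17.0 to 21.3).

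Mural-like cells, which carry smooth muscle or pericyte markers, had a mean share of 8.98% ± 12.2 in IPF and 1.34% ± 2.38 in healthy lungs. A cluster with the contractile genes MYH11, DES and ACTA2 held 148 of its 151 cells from IPF 1, where mural-like cells made up 30.5% (26.6 to 34.8). Another cluster led by the pericyte genes COX4I2 and HIGD1B held 71 cells of healthy 1 and 27 of IPF 3. As a share of mesenchymal cells, mural-like cells made up 17.1% ± 14.6 in IPF and 2.71% ± 3.79 in healthy lungs, above the highest healthy share of 9.21% in 3 of 5 IPF libraries. Mesothelial-like cells, with ITLN1 and MSLN of the pleural lining, made up 3.03% ± 6.78 and 1.41% ± 2.71.

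By exact two-sided permutation tests (n = 5 and 5), 0 of the 10 classes differed between the groups, and 0 had an unadjusted p under 0.05. With 10 classes adjusted for, 1 class alone could not pass even at the smallest possible exact permutation p of 0.00794. The 0 after adjustment therefore does not show that no class differs. The smallest p was 0.0952 for mural-like cells (adjusted p = 0.952), and 0.0556 as a share of mesenchymal cells (adjusted p = 0.389, exact permutation). The difference in fibroblast-like cells (exact permutation p = 0.524) was smaller than the spread between donors, and its sign turned as a share of mesenchymal cells (77.1% ± 14.6 in IPF and 88.1% ± 18.8 in healthy lungs). The log odds of the mural-like share gave an unadjusted p of 0.0476 (exact permutation). With both IPF 1 and healthy 1 left out the unadjusted p was 0.0286 for the percent share (exact permutation). Both were short of the threshold after adjustment. In the latter test every IPF share lay above every healthy share (0.645% to 5.83% against 0% to 0.571%). Its p was thus the smallest these donors can give, and with 10 classes 1 class alone could not pass there either. Without IPF 1 alone the difference in percent share fell from 7.64 to 2.25 percentage points (exact permutation p = 0.206). Clustering without scaling within donors gave an exact permutation p of 0.563. Over all refits with a donor left out, the unadjusted exact permutation p ran from 0.0238 to 0.262.

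**Figure D1:**
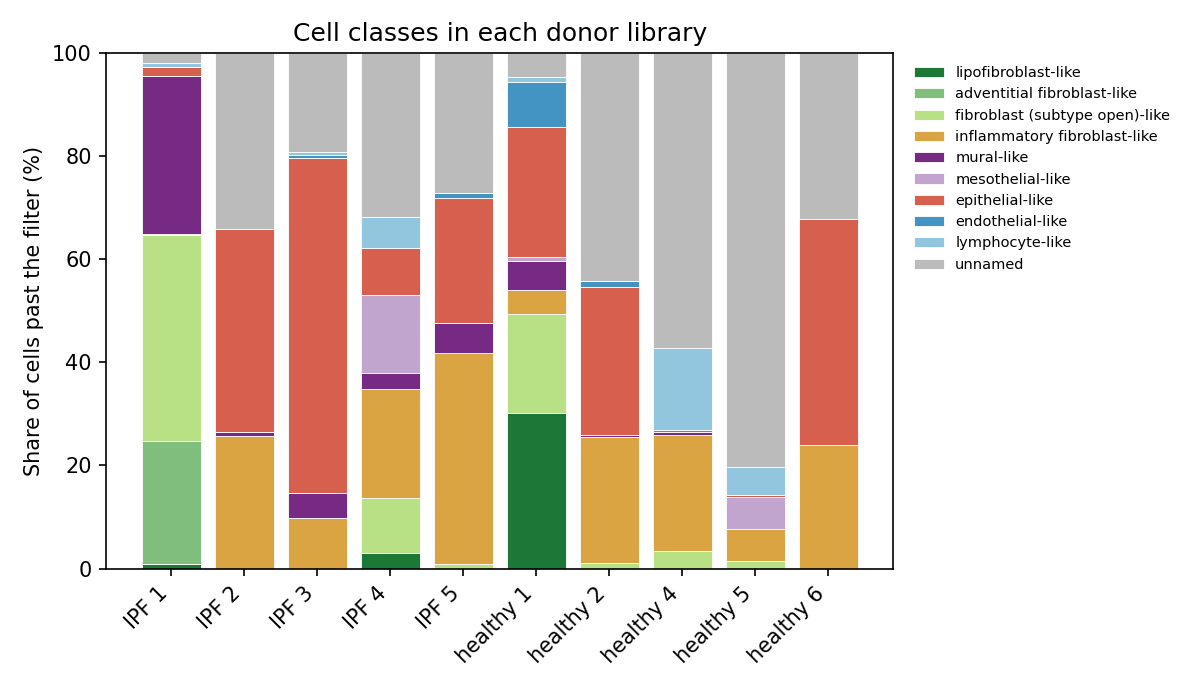
Share of each cell class among the cells past the filter (vertical axis, percent), 1 stacked bar per donor library with no error bars. Inflammatory fibroblast-like cells fill 9.73% to 40.8% of IPF 2 to 5 and 6.22% to 24.3% of healthy 2 to 6, while IPF 1 (0.206%) and healthy 1 (4.73%) hold mostly other fibroblast-like and mural-like cells.

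The sort was meant to remove epithelial, endothelial and blood cells, and the second comparison asked how many cells still carried the sorted markers. EPCAM, a surface protein of epithelial cells, was detected in 39.2% ± 29.3 of IPF cells and 26.4% ± 31.1 of healthy cells (SD, n = 5 and 5). Epithelial-like clusters, with keratins KRT5 and KRT17 or the secretory genes SCGB1A1 and SFTPC, held 27.9% ± 25.3 of IPF cells and 19.7% ± 18.9 of healthy cells, and 65.0% of IPF 3 (61.0 to 68.9). With every cell thinned to 2000 UMIs, EPCAM was detected in 32.0% to 44.0% of epithelial-like cells in the 6 libraries that held both classes. In fibroblast-like cells of these libraries, which should lack EPCAM, it was detected in 0% to 2.33%. Median depth before thinning was 2758 to 25223 UMIs in these epithelial-like cells and 5107 to 42872 in these fibroblast-like cells. PECAM1, the gene of CD31, was detected in 2.06% ± 1.91 of IPF cells and 8.17% ± 8.21 of healthy cells, and PTPRC, the gene of CD45, in 1.27% ± 1.85 and 5.70% ± 8.74.

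The shares did not differ past the threshold in exact two-sided permutation tests (n = 5 and 5) for EPCAM (p = 0.429), PECAM1 (p = 0.103, adjusted p = 0.310) or PTPRC (p = 0.421). Without healthy 6, where 0 of 217 cells had a PECAM1 UMI (which allows a share of up to 1.38%), the exact permutation p for PECAM1 was 0.00794, the smallest these donors can give, and 1 marker passed. At 2000 UMIs per cell the PECAM1 shares were 0.273% ± 0.375 and 2.82% ± 2.83 (exact permutation p = 0.0556). In thinned fibroblast-like cells, which should lack both genes, PECAM1 was detected in 0% to 0.292% of cells per library and PTPRC in 0%. PECAM1 was detected in 52.0% of the endothelial-like cells of healthy 1 and PTPRC in 75.0% of the lymphocyte-like cells of healthy 4, with a median of 2779 and 2084 UMIs before thinning.

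**Figure D2:**
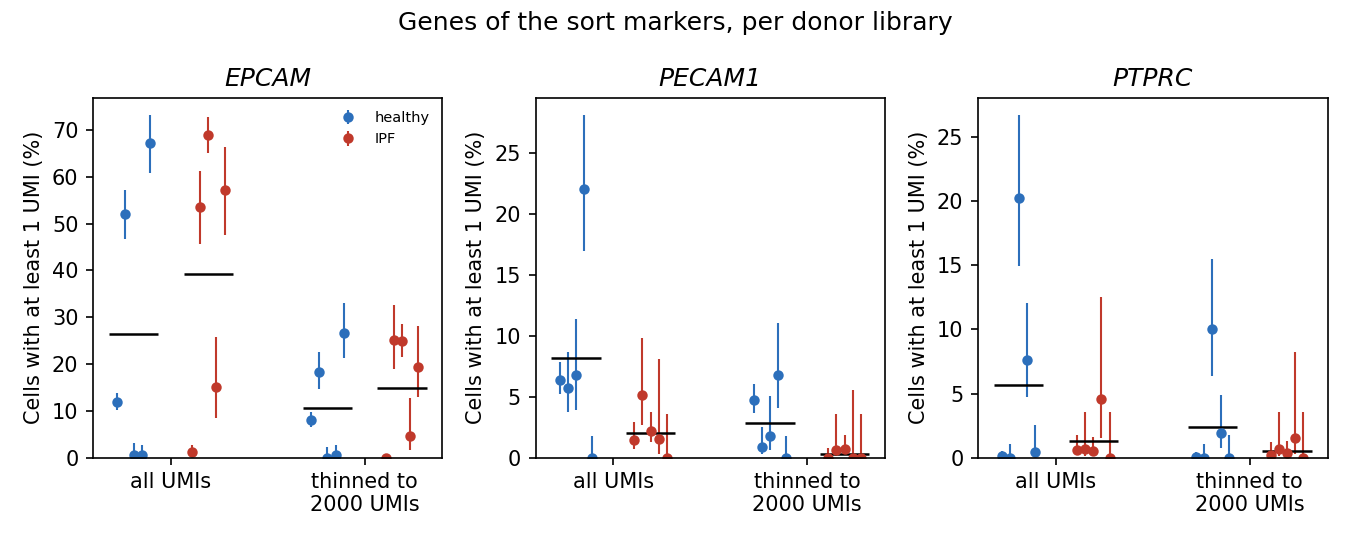
Percent of cells with at least 1 UMI (vertical axes) of EPCAM, PECAM1 and PTPRC, the genes of the proteins used for the sort, with all UMIs and with cells thinned to 2000 UMIs; each point is a donor library with its 95% Wilson interval, blue healthy and red IPF, and black lines are group means. EPCAM splits the libraries of both groups, from 0.478% to 67.3% in healthy and from 1.24% to 69.0% in IPF lungs.

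The third comparison asked which genes differed between IPF and healthy lungs over all sorted cells. ENC1 (ENSG00000171617), an actin-binding protein, was at 42.3 ± 5.45 CPM in IPF and 13.2 ± 6.83 in healthy lungs (SD, n = 5 and 5; log2 fold change 1.45, SE 0.26). FHL2 (ENSG00000115641), a LIM-domain protein of muscle and stroma, was at 177 ± 31.9 and 71.1 ± 31.4 CPM (1.33, SE 0.28). In the other direction, S1PR1 (ENSG00000170989), a sphingosine-1-phosphate receptor of vessels and lymphocytes, was at 2.58 ± 1.28 CPM in IPF and 26.7 ± 18.2 in healthy lungs (-1.89, SE 0.36). The vessel growth factor gene ANGPT2 (ENSG00000091879) was at 16.1 ± 6.87 and 104 ± 85.8 (-2.06, SE 0.50). PLIN2 (ENSG00000147872), a coat protein of lipid droplets, was at 57.4 ± 14.7 and 138 ± 58.2 (-1.15, SE 0.30). All 5 IPF donors lay above the highest healthy donor for ENC1, FHL2, LINC01133 and AVPI1, and below the lowest for S1PR1, PLIN2 and OXSM. These genes were picked by smallest p from the same values, so groups that do not overlap follow in part from the choice. ABL2 had a log2 fold change of 1.05 and PRKCH of -1.07, each with 3 of 5 IPF donors outside the healthy range.

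None of these genes passed the test: limma called 0 of 8808 genes (adjusted p = 1.00 for each gene named here), with 157 at an unadjusted p under 0.05, 93 of them higher in IPF. The 157 were 1.78% of the genes tested, fewer than this unadjusted threshold gives by chance for independent genes. The balance of directions turned with TMM scaling (71 of 153 higher). edgeR called 0 of 11803 (261 unadjusted, 120 of them higher). DESeq2 called 4: ENC1 (adjusted p = 0.00105), S1PR1 and ANGPT2 (both 0.0173), and a gene of the kinds left unnamed. With IPF 1 and healthy 1 left out, limma called 0 (357 unadjusted), edgeR 0 (565) and DESeq2 33.

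Mesenchymal-like cells, which carry the contractile and collagen genes, made up 47.4% ± 31.1 of cells in IPF and 30.1% ± 17.7 in healthy lungs (exact permutation p = 0.333, n = 5 and 5), so lists over all sorted cells also follow the mix of cells. As groups, contractile, collagen and TGF-beta target genes were higher and endothelial, lymphocyte and plasma cell markers lower in IPF. Of 36 lists tested, 21 passed camera, and 0 of them passed with an estimated correlation or by fry. Each p given with an estimated correlation is unadjusted, and none passed the threshold after adjustment. All 14 contractile and smooth muscle genes were higher (median log2 fold change 1.14, adjusted p = 1.16e-06 by camera, p = 0.124 with an estimated correlation). They included the actin-binding TAGLN (1332 ± 995 against 440.7 ± 427 CPM) and the tropomyosin TPM1 (738 ± 240 against 379 ± 178). All 14 fibrillar collagen and collagen processing genes were higher (median 0.64, adjusted p = 1.86e-06 by camera, p = 0.0732 with an estimated correlation). COL1A1 (ENSG00000108821) was at 393 ± 481 against 102 ± 81.6 CPM and BMP1 (ENSG00000168487), which cleaves procollagen, was at 22.9 ± 8.04 against 10.1 ± 3.95. Of 12 TGF-beta target genes 11 were higher (median 0.65, adjusted p = 8.27e-05 by camera, unadjusted p = 0.0157 with an estimated correlation). Among them were TGFBI (58.2 ± 22.6 against 24.1 ± 12.3 CPM) and PMEPA1 (123 ± 60.6 against 66.8 ± 5.74). All 12 fibrosis-associated fibroblast genes were higher (median 0.39, adjusted p = 0.00726 by camera, unadjusted p = 0.0196 with an estimated correlation). The activin gene INHBA was at 163 ± 91.8 against 67.9 ± 43.6 CPM and the matricellular POSTN was at 22.3 ± 16.2 against 10.98 ± 15.1.

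All 7 endothelial markers were lower in IPF (median -1.68, adjusted p = 2.00e-07 by camera, unadjusted p = 0.0314 with an estimated correlation, not past the threshold after adjustment). So were all 10 lymphocyte markers (median -1.22, adjusted p = 1.36e-05 by camera, p = 0.101 with an estimated correlation) and all 6 plasma cell markers (median -2.005, adjusted p = 0.000330 by camera, p = 0.109 with an estimated correlation). CLDN5, a tight junction gene of endothelium, had a log2 fold change of -2.75, the T cell gene CD3D of -1.57 and JCHAIN, the joining chain of antibodies, of -2.97. JCHAIN was at 6879 CPM in healthy 4 and at most 416 in any other donor, and its value ran from -3.86 to -1.25 with a donor left out. The other lists past camera were all higher in IPF: smooth muscle, pericyte, myofibroblast, erythroid, adventitial and open subtype fibroblast markers, adventitial genes, insulin-like growth factor genes, matrix proteases, proteoglycans, basement membrane, WNT pathway, p53 and hypoxia genes. With an estimated correlation their unadjusted p was 0.0189 to 0.390, and none passed after adjustment. No member of any list passed over all genes tested, and adjusted over the list alone only PLIN2 passed, in the alveolar fibroblast and lipofibroblast lists. In these 2 lists the median was positive (0.14 and 0.17) while camera's direction was down (adjusted p = 0.417 and 0.677), and the mean was -0.01 and 0.13.

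IPF 1 and healthy 1 stood apart from the other libraries in these gene groups: across genes, which are not independent replicates, their profiles correlated at 0.874 with each other and at 0.619 to 0.806 with the other 8, which correlated at 0.716 to 0.949 among themselves. The matrix gene DCN was at 6381 and 3555 CPM in them and at 67.3 to 584 in the others. Leaving out IPF 1 ended the camera call of the collagens (median 0.32, adjusted p = 0.09997), contractile genes (0.48, 0.140) and fibrosis-associated genes (0.42, 0.0786), while with healthy 1 left out as well these calls held (0.64, 1.37 and 0.94; adjusted p = 0.000611, 3.18e-05 and 0.00103). Without healthy 5 or healthy 6 the fibrosis-associated genes stood at an adjusted p of 0.0510 and 0.0765, and without healthy 4 the lymphocyte and plasma cell lists at 0.0815 and 0.130. Over all refits with a donor left out, the medians of these lists in turn ran from 0.24 to 0.64, from -1.54 to -0.74 and from -2.71 to -1.23. The call of hypoxia genes ended without IPF 4 (0.13, 0.145), IPF 5 (0.12, 0.236), healthy 1 (0.16, 0.0510), healthy 2 (0.15, 0.0926), healthy 4 (0.0820, 0.161), healthy 5 (0.18, 0.1004) or healthy 6 (0.17, 0.0765). That of p53 genes ended without IPF 3 (0.0724, 0.212), healthy 1 (0.40, 0.0530), healthy 5 (0.19, 0.115) or healthy 6 (0.20, 0.0765). That of erythroid markers ended without healthy 2 (1.80, 0.0843) or healthy 6 (1.73, 0.0765) and that of matrix proteases without healthy 6 (0.45, 0.0533). The erythroid list could be tested in only 9 of the refits with a donor left out. IPF 1 was far the highest of the IPF libraries for it, so its call may rest on that library. Apart from IPF 1, adventitial genes and markers, open subtype and pericyte markers, proteoglycans, basement membrane and WNT genes each lost their call without 3 or 4 of IPF 4 and healthy 2, 4, 5 and 6 (medians 0.17 to 0.60, adjusted p = 0.0606 to 0.217 by camera). The calls of TGF-beta target genes, endothelial markers and myofibroblast markers held with each donor left out in turn.

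The fourth comparison was made within fibroblast-like cells, to reduce the effect of the shares of other cell types, whose RNA was not fully removed: the airway secretory gene SCGB1A1 was at 1.68 to 1181 CPM in the fibroblast-like cells of these donors. It took 5 IPF and 4 healthy donors with 23 to 709 fibroblast-like cells each (healthy 5 had 16). By camera with the preset correlation, collagen genes were higher as a group and genes of alveolar, lipid-storing fibroblasts lower in IPF; neither call held with an estimated correlation, and the alveolar direction turned without healthy 1. COL1A1, the main chain of fibrillar collagen, was at 725 ± 603 CPM in IPF and 249 ± 104 in healthy lungs (SD, n = 5 and 4; log2 fold change 1.3, SE 0.50), above the highest healthy donor in 4 of 5 IPF donors. BMP1 was at 26.1 ± 7.78 and 12.2 ± 2.71 CPM (0.84, SE 0.25), above it in 5 of 5. CTHRC1 (ENSG00000164932), a secreted protein of scar-forming fibroblasts, was at 102 ± 24.0 and 59.1 ± 23.4 CPM (0.79, SE 0.30), above it in 4 of 5.

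Of the 16 fibrillar collagen and collagen processing genes measured, 15 were higher in IPF (median log2 fold change 0.41, adjusted p = 0.00124 by camera, p = 0.119 with an estimated correlation). Of 15 alveolar and lipid-storing fibroblast genes, 3 were higher and 12 lower (median -0.59, adjusted p = 0.0270 by camera, p = 0.337 with an estimated correlation). PLIN2 was at 107 ± 25.6 against 197 ± 85.9 CPM, and the lipoprotein lipase gene LPL had a log2 fold change of -0.69. Among healthy donors PLIN2 was lowest in healthy 1 (72.1 CPM, with 84.1 in IPF 1), which held almost all lipofibroblast-like cells. The difference in PLIN2 therefore does not follow the share of these cells. Lipofibroblast markers, all of them in the alveolar list, gave a median of -0.52 (adjusted p = 0.0388 by camera, p = 0.359 with an estimated correlation). Of 13 mitochondrially encoded genes 11 were lower (median -0.17, adjusted p = 0.0444 by camera, p = 0.1998 with an estimated correlation). MT-ND3 was at -0.40 on the log2 scale, and from -0.65 to -0.16 with a donor left out. The fibrosis-associated list, with 8 of 13 genes higher (median 0.33), did not pass (adjusted p = 0.348 by camera), nor did the 25 other lists tested. With the replicate number as a block, which takes 3 IPF and 3 healthy donors, the collagens kept their call (0.51, adjusted p = 0.000734 by camera), though 0 lists passed in this fit with an estimated correlation or by fry. The alveolar list (-0.26, 0.303), lipofibroblast markers (-0.25, 0.337) and mitochondrial genes (-0.0790, 0.431) lost theirs, as they did in an unpaired fit of these 6 donors (0.356, 0.384 and 0.380). The block added calls of adventitial genes (1.11, adjusted p = 0.00243), adventitial markers (1.04, 0.0132), plasma cell markers (-1.74, 0.00173), immediate early genes (0.36, 0.0425) and inflammatory markers (-0.63, 0.0425), all by camera; in the unpaired fit of these donors the last 2 did not pass (0.384 and 0.135).

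Among single genes, FHL3 (ENSG00000183386), a LIM-domain relative of FHL2, was at 39.1 ± 6.41 CPM in IPF and 16.2 ± 6.14 in healthy lungs (log2 fold change 1.08, SE 0.26). The signalling gene CHN1 was at 35.4 ± 17.7 and 11.1 ± 3.22 (1.27, SE 0.31), and ENC1 was at 54.5 ± 8.39 and 25.6 ± 6.47 (0.98, SE 0.24). RNF24 had a log2 fold change of 0.94 and TUSC3 of 0.86, and for these 5 genes all IPF donors lay above the highest healthy donor. They too were picked by smallest p from the same values. On the lower side, the sphingomyelin synthase gene SGMS1 was at 12.9 ± 4.21 and 24.5 ± 2.87 CPM (-0.75, SE 0.25), ARHGEF7 at -0.68, SQRDL at -0.73 and FARS2 at -0.60 on the log2 scale. None passed: limma called 0 of 8027 genes (adjusted p = 1.00 for each gene named here), with 66 at an unadjusted p under 0.05, 50 of them higher in IPF (29 of 55 with TMM scaling). The 66 were 0.822% of the genes tested, again fewer than chance gives for independent genes. edgeR called 0 (80 unadjusted) and DESeq2 0 (141). With IPF 1 and healthy 1 left out, DESeq2 called 3 genes, S100A8, PLIN2 (adjusted p = 0.00424 each; S100A8 was chosen after its values were seen) and one of the kinds left unnamed, limma 0 (162 unadjusted) and edgeR 0 (237).

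**Figure D3:**
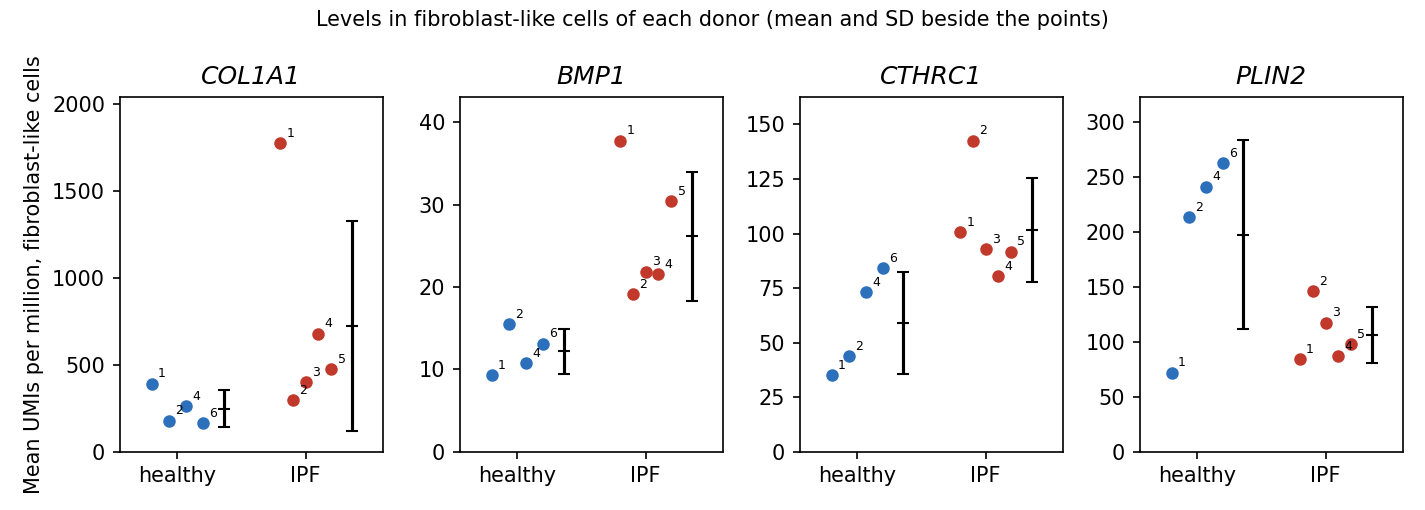
Mean CPM (UMIs per cell on a common scale) of COL1A1, BMP1, CTHRC1 and PLIN2 in the fibroblast-like cells of each donor, 1 point per donor with its number, blue healthy and red IPF; black bars beside the points are the mean and SD. BMP1 is 19.1 to 37.8 in IPF donors and 9.36 to 15.6 in healthy donors, and IPF 1 has 1774 CPM of COL1A1 against 391.75 at most in healthy donors.

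Fibroblast-like cells were of different subtypes in IPF 1 and healthy 1 than in most other donors, and the group calls moved with these libraries. Without IPF 1 the collagen median was 0.11 (adjusted p = 0.704 by camera) and without healthy 6 0.37 (0.0594). Without healthy 1 the alveolar list turned to 1.06 (0.0546), and without IPF 2, 3 or 5 it was -0.26, -0.29 and -0.24 (0.197, 0.404 and 0.177). The call of the mitochondrial list ended without IPF 3 (-0.0596, 0.606), IPF 4 (-0.13, 0.0907), healthy 1 (-0.24, 0.147) or healthy 2 (-0.0451, 0.714). With both IPF 1 and healthy 1 left out the collagens stood at 0.32 (adjusted p = 0.0876) and the alveolar list at -0.04 (0.267), all by camera via limma.

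**Figure D4:**
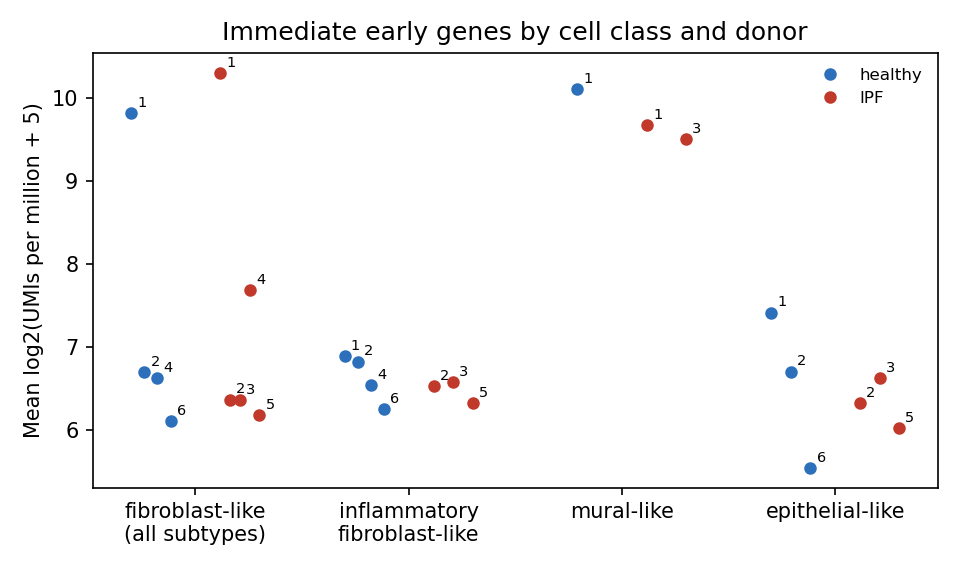
Mean log2(CPM + 5) of 18 immediate early genes, which are induced when tissue is dissociated, by cell class (horizontal axis); each point is a donor with its number, blue healthy and red IPF, shown where a donor has at least 20 cells of the class. In fibroblast-like cells IPF 1 (10.31) and healthy 1 (9.82) lie above the other donors (6.10 to 7.69), while mural-like cells of IPF 3 are at 9.51.

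Mural-like cells were to be compared in the same way, but only IPF 1 (148 cells), IPF 3 (27) and healthy 1 (73) held 20 of them, so values are given for these libraries without a test and without replicates. All 148 mural-like cells of IPF 1 lay in the cluster with MYH11 and DES and 71 of the 73 of healthy 1 in the cluster with COX4I2 and HIGD1B, so their comparison is between 2 kinds of mural-like cell named by such markers. Against mural-like cells of healthy 1, those of IPF 1 had lower pericyte markers (median log2 ratio -2.77) and higher smooth muscle markers (0.62), and contractile genes differed by 0.03. Those of IPF 3 had lower contractile genes (-1.62) and pericyte markers (-1.68) and higher fibrosis-associated genes (1.90), but general fibroblast genes were higher in them as well (SERPINF1 by 4.58, GPC3 3.32, DPT 2.88), so RNA of fibroblasts is not separated from a change in mural-like cells. Whether the effect of IPF differed between fibroblast-like and mural-like cells could not be tested for the same reason.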

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

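Of the tests in this part, those of broad cell class shares and of handling for the libraries that stand apart, the counts over other splits of the donors for genes and lists, those over splits that part all pairs, and the replicate block in thinned cells were chosen after the result was seen; the others were set out before. Within each group of libraries, a value was picked out when the highest or lowest library lay far from its nearest neighbour, measured as that gap divided by the range of the group. This held for 42 of 194 groups of libraries. A rate of 1 in 20, which is 9.7 groups here, would hold by chance only for independent and normally distributed values. The groups reuse the same libraries, and many of their genes and lists were chosen by small p. In some shares of cells, most libraries held no cell of the class, which makes a large gap by construction. The 42 against 9.7 therefore does not measure an excess over chance.

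Healthy 1 was the library concerned in many of them. In the healthy group its gap was 0.850 of the range for cells deposited, 0.867 for the endothelial-like share, 0.897 for the mural-like share, 0.823 for the open subtype share, and 1 for both the lipofibroblast-like and the adventitial fibroblast-like share, the last with 1 cell. Over all sorted cells it was highest in the healthy group for CALD1 (gap 0.774) and for the mean levels of the WNT pathway (0.717), contractile (0.767), open subtype (0.785), proteoglycan (0.735) and smooth muscle (0.739) lists. In fibroblast-like cells it was highest for NPNT (0.916), LPL (0.887) and the alveolar (0.855) and lipofibroblast (0.844) lists, and lowest for PLIN2 (0.837).

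IPF 1 was highest in the IPF group for the mural-like share (gap 0.827), the adventitial fibroblast-like share (1) and the open subtype share (0.735). Over all sorted cells it was highest for VCAN (0.772), for MZB1 (1, the other 4 libraries being at 0) and for the WNT pathway (0.806), basement membrane (0.757), fibrosis-associated (0.8292) and erythroid (0.883) lists. It was lowest for INHBA (0.755) and OXSM (0.87), and in fibroblast-like cells highest for CHN1 (0.739) and NPNT (0.786).

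IPF 4, with 66 cells past the filter, was highest in its group for the lymphocyte-like (gap 0.864), mesothelial-like (1) and lipofibroblast-like (0.728) shares, for cells with PTPRC (0.858), and for JCHAIN (0.918) and the plasma cell list (0.839). IPF 3 was lowest in its group for PLIN2 (0.802). Healthy 4 was highest in its group for DERL3 (0.803) and lowest for BMP1 (0.864) and TGFBI (0.711), and healthy 5 was highest for the mesothelial-like share (0.865) and lowest for INHBA (0.748).

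Among the cells left out by the filter, which no comparison uses, haemoglobin genes made up 80.3% of the UMIs of the 38 IPF cells (117741 of 146675; 95% Wilson interval 80.1 to 80.5), and 32 of these cells had over 50% haemoglobin UMIs. In the 8 healthy cells left out there were 0 of 21641, which allows a share of up to 0.0139%. Most of the 38 IPF cells came from IPF 1, where 517 cells were deposited and 485 kept. The contrast is therefore largely that of 1 library.

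IPF 1 and healthy 1 stood apart from the other 8 libraries in both groups. A difference in sequencing depth could not be decided on. The deviations of the pair from their group means correlated across genes at 0.603 with every cell thinned to one depth. Thinning leaves a gene's expected share of a cell's UMIs unchanged, so this correlation was bound to stay. Different shares of the broad cell classes stay open as a source over all sorted cells. Mesenchymal-like cells made up a larger share of IPF 1 and of healthy 1 than of any of the other 8 libraries. The correlation was 0.810 within fibroblast-like cells, so the pair stood apart within this class as well. That value cannot decide how much the shares add over all sorted cells, and the class itself pools several subtypes. Handling of the tissue that differed between libraries may contribute: immediate early genes in fibroblast-like cells of the pair lay 2.13 on the log2 scale above the nearest other library. The same genes were at 6.89 in the inflammatory fibroblast-like cells of healthy 1, near other donors (6.25 to 6.83), and at 9.51 in mural-like cells of IPF 3, so their level also goes with the cell type. In epithelial-like cells healthy 1 was again highest (7.41 against 5.54 to 6.70 in 5 other donors). Different fibroblast subtypes in the pair, through the way of sampling or through the donors, stay open.

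EPCAM was detected in cells sorted as lacking it. At one depth the share of cells with EPCAM was higher in epithelial-like than in fibroblast-like cells in 6 of 6 libraries, with Wilson intervals apart. EPCAM is itself among the epithelial markers used for naming. This is therefore not an independent test against free RNA from lysed epithelial cells as the whole source. Doublets of a mesenchymal and an epithelial cell are argued against, since collagen genes in epithelial-like cells were at 3.50% of the fibroblast-like level (median over libraries, range 1.77 to 9.61). Free RNA was present for secreted genes, with SCGB1A1 at 1181 CPM in fibroblast-like cells of healthy 6 against 9790 in its epithelial-like cells. How the sort gates were set, or whether EPCAM protein was lost in digestion, was not tested, and no biological explanation was tested.

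Collagen genes were higher in IPF in fibroblast-like cells. Thinning leaves a gene's expected share of a cell's UMIs unchanged, so it cannot decide on sequencing depth as the source. In thinned cells the median log2 fold change was 0.28 with 13 of 16 genes higher (exact sign test p = 0.0213). With the replicate block there the values were 0.63 and 11 of 16 (exact sign test p = 0.210, p = 0.0120 by camera), which alone decides nothing. The sign tests of this list take genes measured in the same donors as independent. Their p therefore does not measure the spread between donors. A different mix of fibroblast subtypes cannot be told apart from a change within them: in inflammatory fibroblast-like cells alone the median was 0.26 with 11 of 16 genes higher (exact sign test p = 0.210, the test set out before; p = 0.00376 by camera; 3 IPF and 4 healthy donors), and COL1A1 was at 296, 403 and 483 CPM in the IPF donors and 164 to 277 in the healthy donors. These cells were not of one cluster: those of the 3 IPF donors and of healthy 2 and 6 (COL1A1 at 177 and 164 CPM) shared a cluster, while those of healthy 1 and healthy 4 (269 and 277) lay in 2 others. Chance cannot be excluded, since 10 of 100 splits of the 9 donors gave a camera p as small as the real 4.13e-05, the smallest of the others being 2.46e-08; of the 18 others that part all 3 pairs of shared numbers, as the real one does, 4 did. A response of fibroblasts to the disease stays open as a hypothesis.

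Counts of genes and lists were set against 100 of the 126 possible splits of the donors. For lists chance cannot be excluded: over all sorted cells the real count was 21 and the highest other 28 (32 of 100 splits as large; 1 of the 12 others that part all 4 shared numbers, with 21), and in fibroblast-like cells 4 and 19 (87 of 100). Of the 18 other splits that part all 3 pairs in fibroblast-like cells, 14 called as many lists (15 at most). For genes the real count was 0 in both comparisons, which any split reaches (100 of 100 each), so the splits decide nothing there; the highest others were 2 over all sorted cells and 352 in fibroblast-like cells. The split that called 352 genes keeps IPF 1 and healthy 1 on one side, while splits that part them called 0 at most, which points to a structure of the samples other than the disease.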

How the results depend on the processing

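The alternatives without both IPF 1 and healthy 1, and with only the donors of shared number in an unpaired fit, were chosen after seeing the data; the others were set out before. Limits of the tests: in thinned cells the smallest adjusted p over all sorted cells was 0.0884 by limma, and with no filter on low values 0 of 25192 and 0 of 22346 genes passed (525 and 333 unadjusted). Depth limits shares of cells with a weakly expressed gene. Healthy 5 had too few fibroblast-like cells for the fourth comparison. A minimum of 50 fibroblast-like cells was not run, since only IPF 1 and 3 and healthy 1, 2 and 6 have them, and the alternatives for mural-like cells and for the difference between cell types had no test to repeat.

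Over all sorted cells limma called 0 genes under each alternative run and with each donor left out, and with all donors edgeR called 0 and DESeq2 4. In fibroblast-like cells limma called 0 likewise, and with all donors edgeR and DESeq2 0; unadjusted counts are those of the report. Under each alternative run 0 classes differed in share, though with all 10 donors and 10 classes 1 class alone could not pass. The count of sort markers was 0 to 1 with a donor left out, 1 without healthy 6. Lists by camera, 21 over all sorted cells and 4 in fibroblast-like cells, fell to 0 and 0 with an estimated correlation and to 0 and 0 by fry, whose construction allows for correlated genes. In fibroblast-like cells the number was 1 with a pseudocount of 1 (the cause was not tested).

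With a donor left out, lists over all sorted cells numbered 10 to 25: 12 without IPF 1, 12 without healthy 2, 10 without healthy 6 and 25 without healthy 1. In fibroblast-like cells they numbered 3 to 12: 12 without IPF 1, 7 without healthy 4, 7 without healthy 6 and 3 without IPF 2. Without both IPF 1 and healthy 1 they were 18 and 4. Without IPF 1 the calls of insulin-like growth factor genes (0.42, adjusted p = 0.285 by camera), smooth muscle markers (0.40, 0.537), pericyte markers (0.28, 0.912), matrix proteases (0.23, 0.521) and proteoglycans (0.13, 0.725) also ended.

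Some signs turned. HAS2 was -0.0235 by edgeR on summed UMIs and -0.00673 by DESeq2 on summed UMIs, VCAN -0.0451 with donor weights, and RGCC in fibroblast-like cells 0.51 at a higher clustering resolution and 0.18 without scaling within donors, against -1.13. As a share of mesenchymal cells, fibroblast-like cells differed by -10.9 percentage points and mesothelial-like cells by -3.53, by construction of the smaller total. Mesothelial-like cells were at -0.147 in log odds, epithelial-like at -5.89 without the donors titled raw, and without both IPF 1 and healthy 1 endothelial-like cells were at 0.0921 and the adventitial gene list at -0.0778. Except where stated, the cause was not tested.

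With a donor left out, signs turned without IPF 1 (the lower value) over all sorted cells: adventitial genes -0.28 to 0.90, adventitial markers -0.0350 to 0.93, WNT pathway -0.0340 to 0.83, open subtype markers -0.16 to 1.21, and basement membrane 0.0730 to 0.89, where camera's direction turned. In fibroblast-like cells RGCC was -2.21 (without IPF 1) to 0.66 (without healthy 1), the alveolar list -1.37 to 1.06 and lipofibroblast markers -1.38 to 1.06, with the same donors. Epithelial-like shares differed by -1.08 (without IPF 3) to 14.7, endothelial-like by -2.14 to 0.0166 (without healthy 1) and mesothelial-like by -1.41 (without IPF 4) to 2.82. The cause was not tested.

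With the replicate number as a replicate block, limma called 0 genes in both comparisons (419 and 266 unadjusted) and camera 23 and 6 lists (0 and 0 with an estimated correlation, 0 and 0 by fry). Shares gave 0 classes with the block, but 4 pairs cannot give an exact permutation p under 0.05. Over all sorted cells the numbers do not pair the donors: same-number deviations correlated at 0.624, 0.610, 0.289 and 0.0126 for numbers 1, 2, 4 and 5, best with the own number for 1 and 2 only. There 20 of the 21 calls held, the p53 list (0.13, adjusted p = 0.501) not, and 3 others were added. In fibroblast-like cells, where each of 3 correlations is over 0.1, the collagen call held and 3 ended (alveolar, lipofibroblast and mitochondrial lists), while 5 others, given in the report, were added. The same 6 donors in an unpaired fit gave 4 lists and ended the same 3 calls, so these ended with the donors left out; 19 lists passed in the 8 donors over all sorted cells. Of named genes under alternatives, 1546 comparisons over all sorted cells kept side and direction, 3 reversed and 3 passed the threshold, and in fibroblast-like cells 585 kept it and 3 reversed. These counts leave out DESeq2 without both IPF 1 and healthy 1, which called ENC1, S1PR1, ANGPT2, PLIN2 and CALD1 over all sorted cells and PLIN2 in fibroblast-like cells. TMM scaling lowered the share of unadjusted genes higher in IPF from 59.2% to 46.4% and from 75.8% to 52.7%.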

Other observations

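All genes, clusters and list values of this part were chosen after their values were seen, and the lists themselves were fixed before. Fibroblast-like cells of IPF 1 and healthy 1, the 2 libraries that stood apart, were set against each other with 1 library each and so without replicates. Their cells lie in different clusters: 116 of 117 cells named adventitial fibroblast-like are from IPF 1 and 396 of 402 named lipofibroblast-like from healthy 1. The values below therefore describe different kinds of fibroblast, and the direction of adventitial and alveolar genes follows from the naming. Adventitial fibroblast genes were higher in IPF 1 (11 of 12, median log2 ratio 3.57), such as PLA2G2A (1883 against 13.99 CPM), MFAP5 (471 against 6.48), SFRP2 (2820 against 153) and the stem and progenitor surface marker CD34 (169 against 9.02). Insulin-like growth factor genes (7 of 10, median 2.41) and interferon response genes (14 of 16, median 1.29) were higher too, IFI6 and IFI27 being among the leading genes of the adventitial cluster. Of the fibrillar collagen and collagen processing genes 16 of 17 were higher (median 1.02), with COL3A1 at 1287 against 138 CPM, and the WNT inhibitor SFRP4 was at 831 against 56.1. Alveolar fibroblast genes were lower (2 of 15 higher, median -1.76), with the alveolar matrix gene NPNT at 14.1 against 200 CPM, RGCC at 781 against 3566 and LPL at 9.13 against 110. The alveolar gene A2M differed little (3297 against 3060).

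Mural-like cells of IPF 3 (27 cells) had higher complement genes than those of healthy 1 (11 of 11, median log2 ratio 2.75), higher adventitial genes (9 of 11, 2.42) and higher chemokines and cytokines (14 of 15, 1.48). The same limit holds here, with A2M higher by 2.42 and the contractile MYL9 (-1.98) and TPM2 (-2.32) lower: RNA of fibroblasts is not separated from a change in mural-like cells. Mural-like cells of IPF 1 had higher interferon response genes (8 of 9, median 1.03) and lower heat shock genes (2 of 12 higher, -1.03) than those of healthy 1. Each is 1 library against 1, without a test.

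Clusters left unnamed held 22.9% ± 13.1 of IPF cells and 43.8% ± 28.3 of healthy cells (SD, n = 5 and 5). The largest of them, with 265 cells, held 97 cells of healthy 4 and 131 of healthy 5. Immunoglobulin genes and JCHAIN led it, but JCHAIN was detected in 99.0% of the unnamed cells of healthy 4 and in 0 of 168 of healthy 5. In healthy 4 it was also detected in 89.1% of fibroblast-like cells, though at 306 against 11731 CPM, so detection alone does not set the cell kind there. PECAM1 was detected in 26.8% of the latter and 8.82% of the former. Another, which met the epithelial list but had more markers of another class among its 10 leading genes, is not in the epithelial-like shares. It was led by secretory and defence genes of airway epithelium (S100A9, SCGB3A1, LCN2, MUC1) and held 9.67% ± 9.29 of IPF cells and 5.70% ± 8.84 of healthy cells. A cluster led by CLU, the WNT inhibitor WIF1 and the matrix gene ASPN held 43 of its 45 cells from healthy 1. A cluster led by STC1, BMP2 and ANGPT2, genes of secreted signals, held 72 cells of healthy 2 and 18 of IPF 3, of 120.

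Epithelial-like cells were of several kinds. A cluster with the basal cell genes S100A2, KRT5 and KRT17 held 195 of 253 cells from IPF 3, one led by S100A2, LAMB3 and KRT17 held 225 of 227 from healthy 1, and one with the surfactant genes SFTPC and SFTPB held 33 of 68 from healthy 6. Cells named endothelial-like came mostly from healthy 1, in a cluster with the capillary genes FCN3 and CA4 (64 of 68 cells) and one with the lymphatic genes CCL21 and TFF3 (49 of 53). Healthy 5 had more CLDN5 over all its cells (412 against 268 CPM in healthy 1) and more cells with PECAM1 (22.0% against 6.402%), but none of its cells lie in these clusters.

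Lists not past camera over all sorted cells were elastic fibre genes (13 of 14 higher, median log2 fold change 0.52) and epithelium-directed growth factors (9 of 11, 0.23), both at an adjusted p of 0.0518. The others were macrophage markers (0.126), metallothioneins (0.243), immediate early (0.257), interferon response (0.347), heat shock (0.428), mitochondrially encoded (0.499), cholesterol synthesis (0.548), epithelial markers (0.549), inflammatory fibroblast markers (0.753), chemokines (0.809) and complement genes (0.993), n = 5 and 5. In fibroblast-like cells myofibroblast markers came nearest of the 26 lists not past camera (10 of 14 higher, median 0.36, adjusted p = 0.0594), then heat shock genes (3 of 12 higher, -0.17, 0.0931). Mast cell, mesothelial, Schwann cell and proliferation markers had too few measured genes for a test.

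Scrublet called 40 cells doublets. Over the 20 pairs of libraries within a group, profiles differed by a chi-square per degree of freedom of 18.6 to 229, so 0 pairs looked like a file deposited in duplicate.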
